A study of Mus musculus with 10 samples.

How the data were processed

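RNA was measured in 10 libraries of sorted mouse intestinal stem cells, 1 library per animal. Per the labels' protocols, RNA was extracted with TRIzol LS and a spin-column clean-up, full-length cDNA was made and amplified with the SMART-Seq v4 kit for low input, libraries were built by tagmentation with Nextera XT, and sequencing ran on a NextSeq 500. These kits add no molecular identifiers and do not mark the strand, so amplified copies count as separate reads and a gene cannot be told from an overlapping antisense transcript.

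The authors deposited a table of estimated counts per gene symbol and a table of TPM (transcript abundance scaled to a fixed total per library) for the same 30295 gene rows and 10 libraries. Estimated counts that are not whole come from dividing reads among the transcripts they fit. The submitters' processing notes name kallisto and edgeR, with no version, and the build GRCh38, which is a human build, while the deposited gene symbols are mouse symbols. How transcripts were summed to genes, the annotation and any filter are not given in the sources used here. Of the symbols, 28423 (93.8%) are in the GENCODE M21 mouse annotation, which served only for transcript length and GC content. The deposited TPM columns sum to 943114 to 972945, so some transcripts lie outside these rows. Another 27 rows carry names that a spreadsheet turned into dates, and they stayed in the library totals and tests without being named. Reads shared by near-identical copies can move between them from library to library, and 53 tested rows hold the same estimated counts as another row. Predicted genes (Gm followed by a number), pseudogenes (-ps) and families such as the alpha-defensins (Defa), metallothioneins (Mt) and cytochrome P450 genes (Cyp) are therefore uncertain as single genes.

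Samples were grouped by their labels into Lgr5 cells from mice fed ad libitum (Lgr5 AL, n = 3) or under calorie restriction (Lgr5 CR, n = 3), and Hopx cells from mice fed ad libitum (Hopx AL, n = 2) or under calorie restriction (Hopx CR, n = 2). Per the labels' protocols and design text, animals were handled in 5 isolations, each holding 1 AL and 1 CR animal of the same reporter line. No pair of libraries held identical values, and the correlation of log2 CPM between libraries of a group was 0.958 to 0.984.

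The estimated counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr at its minimum count of 10, which left 15839 genes, and libraries were scaled by the trimmed mean of M-values (TMM). A model with a mean for each of the 4 groups was fitted to all 10 libraries with edgeR's quasi-likelihood method (edgeR 4.0.16, R 4.3.3), so that groups of 2 and 3 borrow their spread from the whole series. The biological coefficient of variation was 0.389. The 5 contrasts were CR against AL in Lgr5 cells, CR against AL in Hopx cells, the difference between these diet effects (interaction), Hopx against Lgr5 cells under AL, and Hopx against Lgr5 cells under CR. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. Levels are TMM-normalized CPM (counts per 1e6 counts of the library), given as mean ± SD.

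Before the data were examined, 35 gene lists, the contrasts, the tests, the alternatives and the rule for named genes were fixed. The lists cover the cell types of the crypt and villus, other cells a sort could hold, stem cell and cell cycle genes, nutrient signalling, metabolism, translation and stress, and 34 of them had at least 5 tested members. A total of 9 members were found under another symbol. Each list was tested against all other genes with camera (limma 3.58.1) at its preset correlation between genes of 0.01, adjusted over the 34 lists, and again with the correlation estimated from the data. The fry test (limma), which asks whether a list changed at all and not whether it changed more than other genes, was run beside it. Members were also adjusted over the list alone. Lists overlap in part, for example 13 genes between the active stem cell and Wnt target lists and 2 between the enterocyte and fatty acid oxidation lists. A second tuft cell list, a second enterocyte list and a list of xenobiotic metabolism families were added after the first results had been seen.

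The rule for named genes took, per contrast, the genes past the threshold with at least 5 CPM in the higher group, CPM values that do not overlap between the groups, and a symbol that is not a predicted gene, clone, pseudogene or mitochondrial gene, ranked by fold change. With fewer than 5 such genes it took the 10 with the smallest p by the same expression and symbol rules, and this was the case in all 5 contrasts. It added up to 4 members of each described list with the smallest p, and fixed genes that include Lgr5, Hopx, Olfm4, Ascl2, Mki67 and Mtor. The genes past the threshold that the rule leaves out (Gm10698, Gm9765, Gm5499 and Rps13-ps1) are named as well and were chosen after their values were seen, as were Hpgds, Lrmp, Siglecf, Npc1l1, Abcg8, Cyp2c29, Cyp2c55, Cyp2j6, Gstm4, Gsta1 and Ugt2b5.

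Library depth was 20.3 to 39.9 M estimated counts in Lgr5 AL, 30.2 to 78.3 M in Lgr5 CR, 37.6 to 72.1 M in Hopx AL and 45.6 to 87.2 M in Hopx CR. A gene with no counts in a group was set to a floor of 3 counts over the group, which is 0.0238 CPM in Hopx CR. Floors and intervals cover counting error only. No list's median moved when members with no counts in a group were set to that floor. The steps were tested on simulated counts with 200 changed genes, drawn from genes with a mean of at least 5 CPM. Simulated genes varied independently of each other and without an isolation effect, so the shares recovered need not hold for the real libraries. The edgeR test recovered 26% of 2-fold and 91% of 4-fold changes for Lgr5 CR against AL (15464 genes run), 7% and 73% for Hopx CR against AL (15446 genes run), and 16% and 82% for Hopx against Lgr5 under AL (15472 genes run), with 3, 7 and 3 false calls.

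The isolation number pairs the CR and AL animals, because the labels give it as a shared batch. Deviations from the group means of animals of the same isolation correlated across genes with r = 0.076, 0.16 and 0.019 in the Lgr5 isolations and 0.025 in the Hopx isolations. With 2 libraries per Hopx group the deviations mirror each other, so the Hopx isolations share this 1 value by construction. The main model has no isolation term, and a fit with isolation as a block was made for the diet contrasts. Isolation cannot be a fixed term between populations, since no isolation holds both, so limma-voom with isolation as a random effect was used there (consensus correlation 0.158). The other alternatives were RLE and upper-quartile scaling, no low-count filter, a filter of 10 CPM in 2 libraries, DESeq2 1.42.0, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a TPM of at least 1 in 2 libraries, fits of only the groups compared, a 2-fold minimum, and each library left out in turn. The TPM values got no further scaling between libraries. When a Hopx library is left out its group has 1 library, which is assumed to vary like the others. A correction of each library's trend with transcript length and GC content, and a term for the sex of the animals, were added after seeing the data. The sex term was the presence of Y-linked transcripts in a library and did not come from the labels. Alternatives were tabulated for the described lists, a restriction made after sign changes in 6 other list and contrast pairs had been seen, and those pairs are not described. All columns of both tables were used.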

Results

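Gene expression was compared between the active and the reserve stem cells of the mouse intestine, and between diets within each population. Active stem cells were sorted by flow cytometry from mice with an EGFP reporter at the Lgr5 locus, which marks the dividing cells at the crypt base. Reserve stem cells were sorted from mice in which Hopx-CreER switches on tdTomato, which marks slowly dividing cells that can replace the active pool after injury. The mice were C57Bl/6 and had free access to food (AL) or were under calorie restriction (CR). The 10 libraries, from 10 animals in 5 isolations, form 4 groups: Lgr5 AL (n = 3), Lgr5 CR (n = 3), Hopx AL (n = 2) and Hopx CR (n = 2). Depth ran from 20.3 M estimated counts in Lgr5 AL replicate 3 to 87.2 M in Hopx CR replicate 1, and 15839 genes were tested.

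Lgr5 mRNA was 155 ± 91 CPM in Lgr5 AL, 219 ± 62 in Lgr5 CR, 78.6 ± 12 in Hopx AL and 114 ± 63 in Hopx CR (SD). Hopx mRNA was 127 ± 9.2, 150 ± 4.4, 108 ± 4.0 and 99.1 ± 24 CPM in the same order. Its mean was thus not higher in the cells sorted by the Hopx reporter, and the name reserve stem cells rests on the sort. Transcripts of differentiated cells were abundant in every library. Lyz1, the lysozyme of Paneth cells, took from 0.677% of counts in Lgr5 AL replicate 3 to 9.39% in Hopx AL replicate 1, where the 5 highest genes took 17.8%. The libraries also differed in Y-linked transcripts. Eif2s3y, a Y-linked gene, stood at 0.045 TPM in Lgr5 AL replicate 3, 0.0766 in Lgr5 CR replicate 3 and 0.125 in Hopx CR replicate 1, and at 8.91 to 30.5 in the other 7 libraries, so the animals of isolation 4 differed in it.

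The first question was how calorie restriction changes active stem cells. In Lgr5 CR, 3 genes rose. Tmprss15, the brush-border protease that activates trypsinogen, rose from 6.10 ± 1.3 to 49.4 ± 6.6 CPM (log2 fold change 3.02, SE 0.317, adjusted p = 0.0407). Papss2, which makes the sulfate donor of sulfation reactions, rose from 196 ± 12 to 636 ± 120 CPM (1.69, SE 0.2, adjusted p = 0.0416). Mt2, a metallothionein that binds zinc and copper, rose from 4.21 ± 1.3 to 29.7 ± 9.2 CPM (2.82, SE 0.336, adjusted p = 0.0416). Each was higher in the CR animal of all 3 isolations, by 2.70 to 3.59, 1.26 to 1.94 and 1.97 to 3.78 log2 units. The next genes by p did not pass. Socs3, an inhibitor of cytokine signalling, differed by 2.66 (adjusted p = 0.0816). They also include the drug exporters Abcb1a (3.13) and Abcc2 (2.59), the glutathione transferase Gstm1 (2.53, 122 to 704 CPM) and the fatty acid hydroxylase Cyp4a10 (3.72), these 4 at adjusted p = 0.134. The threonine aldolase Tha1 (1.27, adjusted p = 0.145) and the gasdermin Gsdma (2.51, adjusted p = 0.162) follow. Stem cell genes did not pass either: Lgr5 differed by 0.50, Olfm4 by 0.25, Hopx by 0.25 (adjusted p = 0.647) and Ascl2, a transcription factor of active stem cells, by -0.82 (adjusted p = 0.454).

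**Figure D1:**
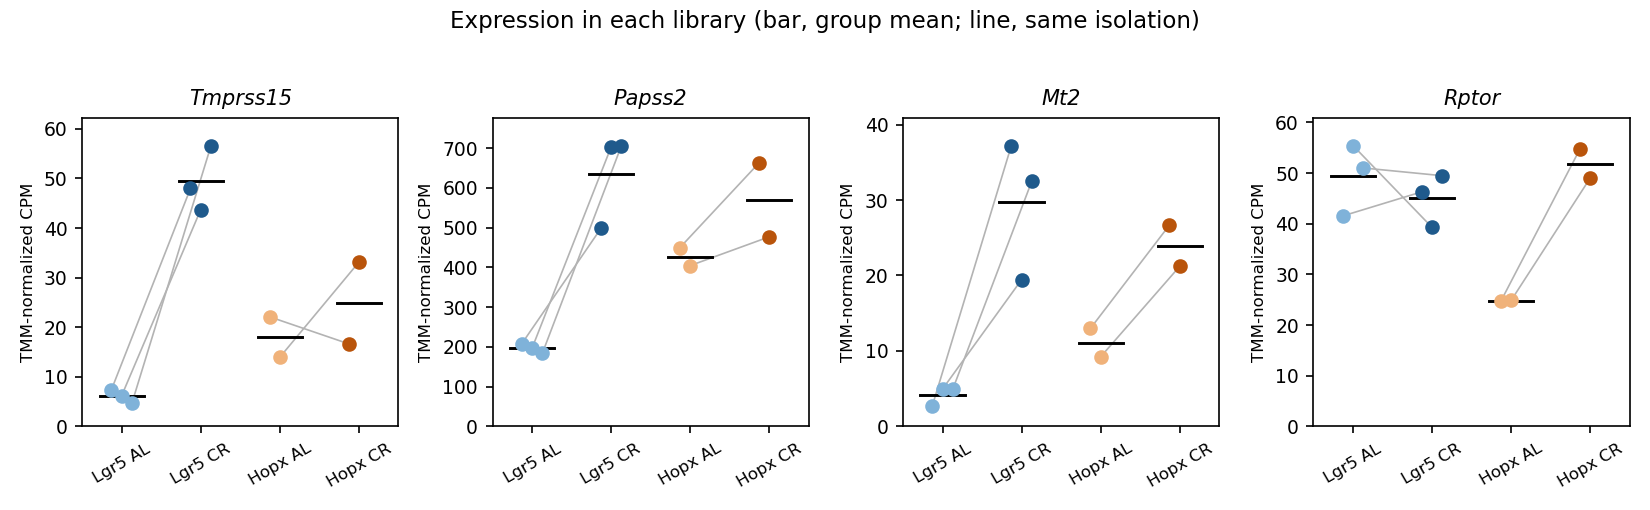
TMM-normalized CPM (vertical axes) of Tmprss15, Papss2, Mt2 and Rptor in each of the 10 libraries, by group (horizontal axes), with points for libraries, bars for group means and thin lines for the same isolation. All 3 Lgr5 CR libraries lie above all 3 Lgr5 AL libraries for Tmprss15, Papss2 and Mt2, and both Hopx CR libraries (49.0 and 54.7 CPM) lie above both Hopx AL libraries (24.7 and 24.9) for Rptor.

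Of 34 lists, 8 passed camera at its preset correlation in Lgr5 CR against AL, 4 higher and 4 lower. None of the 8 calls held with an estimated correlation, where the smallest adjusted p over the lists was 0.697, and fry passed none (smallest adjusted p = 0.287). All 21 tuft cell markers, the genes of the chemosensory cells of the epithelium, were lower (median -1.75, camera adjusted p = 1.34e-23), and 17 passed when adjusted over the list alone and 0 over all genes. The kinase Dclk1 differed by -1.98, the taste channel Trpm5 by -1.75 and the transcription factors Gfi1b and Spib by -2.22 and -2.03. All 33 enterocyte genes were higher (median 0.87, adjusted p = 6.84e-16; 5 adjusted over the list alone, 0 over all genes), among them the disaccharidase Sis (1.63), the lipoprotein Apob (1.91), the fructose transporter Slc2a5 (2.37) and Cyp3a11 (2.49). Genes of fatty acid oxidation and PPAR targets were higher for 33 of 39 (median 0.42, adjusted p = 6.43e-11; 10 adjusted over the list alone, 0 over all genes), with Acadl and Acaa1b, enzymes of mitochondrial and peroxisomal oxidation, at 1.23 and 2.64. All 40 genes of S phase were lower (median -0.42, adjusted p = 5.97e-12, 0 adjusted over the list alone), such as the replication licensing genes Cdc6 (-1.13) and Cdt1 (-0.60). Of 27 genes of cholesterol synthesis 23 were lower (median -0.41, adjusted p = 4.5e-07; 3 adjusted over the list alone, 0 over all genes), with Cyp51 at -1.08 and Idi1 at -0.82. Autophagy and lysosome genes were higher for 33 of 41 (median 0.18, adjusted p = 0.00167, 0 adjusted over the list alone), with the mitophagy receptor Bnip3 at 1.07.

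These 6 lists moved the same way in all 3 isolations, by -2.44 to -0.69 for tuft cell, 0.32 to 2.00 for enterocyte, 0.34 to 0.96 for fatty acid oxidation, -0.58 to -0.37 for S phase, -0.41 to -0.19 for cholesterol synthesis and 0.12 to 0.37 for autophagy, in mean log2 CPM. Such agreement is expected of lists picked by their group difference, and some lists that did not pass camera agreed in all 3 isolations too. The 6 lists also passed with any single Lgr5 library left out, though the sizes moved. The enterocyte median was 0.47 without Lgr5 AL replicate 3 and 1.77 without Lgr5 AL replicate 1. The other medians ranged over -2.13 to -1.53 (tuft cell), 0.29 to 0.64 (fatty acid oxidation, highest without Lgr5 AL replicate 1), -0.56 to -0.33 (S phase), -0.44 to -0.26 (cholesterol synthesis, smallest without Lgr5 AL replicate 2) and 0.145 to 0.251 (autophagy).

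Paneth cell genes were higher for 15 of 20 (median 0.36, adjusted p = 0.00133), with Defa20 at 3.23, and the call ended without Lgr5 AL replicate 3 (median 0.03, adjusted p = 0.785). The Notch pathway list mixes receptors, ligands and targets with secretory-lineage factors such as Neurog3 and Atoh1, so its median gives no direction of Notch signalling. Its genes were lower for 13 of 19 (median -0.34, adjusted p = 0.0246), with Neurog3 at -2.34. That call ended without Lgr5 AL replicate 2 (median -0.15, adjusted p = 0.0617), Lgr5 CR replicate 1 (-0.31, adjusted p = 0.0781) or Lgr5 CR replicate 2 (-0.33, adjusted p = 0.0544), and with the length and GC correction (-0.25, adjusted p = 0.124). With any single Lgr5 library left out the Notch median ranged over -0.374 to -0.0868. The active stem cell list (median 0.09, adjusted p = 0.538) and the list of mTORC1 components and regulators (median 0.11, adjusted p = 0.726) did not pass, and their medians were -0.05 and -0.09 on the TPM scale, where the median of all genes shifted by -0.19. Without Lgr5 AL replicate 3 the active stem cell list passed as higher (0.38, adjusted p = 1.25e-04), and without Lgr5 AL replicate 1 its median was -0.08 (adjusted p = 0.184). Every other way of splitting the 6 Lgr5 libraries into 3 and 3 also passed 8 or more lists by camera.

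The gene count depended on the fit. With isolation as a block, edgeR called 0 genes in Lgr5 CR against AL (adjusted p = 0.121 for Tmprss15 and Mt2 and 0.114 for Papss2), with 1830 genes at an unadjusted p under 0.05 against 1549 without the block, where 792 would come by chance. DESeq2 called 360 genes, 201 higher and 159 lower, and these include the 3. The edgeR count was 109 without Lgr5 AL replicate 1, 0 without any other Lgr5 library, 7 and 9 without Hopx AL replicates 1 and 2, and 1 without Hopx CR replicate 1 or 2.

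The second question, and the one the series title puts first, was how reserve stem cells respond to calorie restriction. In Hopx cells 2 genes fell, both predicted genes and therefore uncertain. Gm10698 had no counts in Hopx CR and was at least 283-fold lower there than in Hopx AL (6.73 ± 0.28 CPM, adjusted p = 0.00102, against a floor of 3 counts over the group). Gm9765 fell from 37.9 ± 20 to 0.144 ± 0.14 CPM (-7.89, adjusted p = 0.0328). The genes of the mTORC1 pathway nearest to the threshold did not pass over all genes. Rptor, the scaffold subunit of mTORC1, stood at 24.8 ± 0.11 CPM in Hopx AL and 51.9 ± 4.0 in Hopx CR (log2 fold change 1.07, SE 0.198, adjusted p = 0.406). Mtor, the kinase itself, stood at 31.8 ± 3.3 and 60.1 ± 6.0 CPM (0.92, SE 0.237, adjusted p = 0.469). Tsc2, an inhibitor of the complex, stood at 52.5 ± 3.6 and 93.3 ± 5.4 CPM (0.83, SE 0.191, adjusted p = 0.455). These 3 were higher in the CR animal of both isolations, by 0.98 to 1.15, 0.92 in each and 0.70 to 0.96 log2 units, and passed when adjusted over the list alone. Rptor and Tsc2 were named for their small p, so agreement of the isolations follows in part from that choice. Mtor was fixed beforehand. In Lgr5 cells Mtor was also higher under CR (log2 fold change 0.477, edgeR unadjusted p = 0.0327). There the CR animal was higher in 2 and lower in 1 of the isolations for Mtor (-0.0594 to 0.755) and Tsc2 (-0.151 to 0.518). For Rptor it was higher in 1 and lower in 2 (-0.497 to 0.156).

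Across the 39 mTORC1 components and regulators, 23 were higher and 16 lower in Hopx CR (median 0.05, adjusted p = 0.209), and the 39 targets of mTORC1 and ATF4 had a median of -0.01, with 19 higher and 20 lower. The targets passed as higher without Hopx AL replicate 1 (median 0.22, adjusted p = 0.0457) and as lower without Hopx AL replicate 2 (-0.22, adjusted p = 0.00485), and their median was 0.28 on the TPM scale, where that of all genes shifted by 0.27. Another gene with a small p was Capn15, a calpain-like protease, with 2 counts in Hopx AL and 995 in Hopx CR (ratio 396, 95% counting interval 109 to 3280, adjusted p = 0.217). Zc3h4 (1.97) and the RNA-binding gene Rbm45 (-2.91) stood at adjusted p = 0.238 and Card14 (1.06) at 0.289. At adjusted p = 0.406 were the ubiquitin ligase Ube4b (1.14), the laminin subunit Lamb3 (1.41), the heme-binding Hebp1 (-2.97), Lrch4 (0.91) and Vav2 (0.93). Hopx differed by -0.13 and Lgr5 by 0.54 and did not pass.

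Of 34 lists, 12 passed camera in Hopx CR against AL, 5 higher and 7 lower. None of the 12 calls held with an estimated correlation (smallest adjusted p = 0.726) and fry passed none (smallest adjusted p = 0.42). Genes of fatty acid oxidation and PPAR targets were higher for 38 of 39 (median 0.57, adjusted p = 1.58e-14; 7 adjusted over the list alone, 0 over all genes), with the fatty acid transporter Cd36 at 2.48, the thioesterase Acot1 at 1.45 and Acadl at 0.95. Enterocyte genes were higher for 32 of 33 (median 1.06, adjusted p = 1.73e-10; 2 adjusted over the list alone, 0 over all genes), with Apob at 2.08, Cyp3a11 at 2.51 and the peptidase Mep1a at 1.42. Genes of G2 and M phase were higher for 38 of 40 (median 0.45, adjusted p = 4.34e-08, 0 adjusted over the list alone), such as the mitotic genes Gtse1 (1.37), Plk1 (0.75) and Kif20a (0.73). Markers of immune cells were lower for 23 of 25 (median -1.65, adjusted p = 5.11e-07, 0 adjusted over the list alone), with the T cell genes Cd8a and Lck at -1.73 and -1.67. Interferon response genes were lower for 25 of 30 (median -0.63, adjusted p = 1.38e-04, 0 adjusted over the list alone). In isolations 4 and 5 lists that did not pass could also move the same way, such as mTORC1 components and regulators (0.307 and 0.0336). Agreement between these isolations therefore does not set a list apart. The 5 lists above moved the same way in isolations 4 and 5, by 0.47 and 0.96 (fatty acid oxidation), 0.75 and 1.24 (enterocyte), 1.06 and 0.17 (G2 and M phase), -1.92 and -0.89 (immune cell) and -0.42 and -0.77 (interferon response). They passed with any single Hopx library left out, though the sizes moved. G2 and M phase was 0.21 without Hopx AL replicate 1 and 0.68 without Hopx AL replicate 2. Without Hopx CR replicate 2 interferon response was -0.40 and immune cell -2.49, and without Hopx AL replicate 2 interferon response was -0.41.

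Enteroendocrine genes were lower for 31 of 32 (median -0.70, adjusted p = 4.47e-06), with Pcsk1n at -1.80 and Pax4 at -1.44, a call that ended without Hopx CR replicate 2 (median -0.37, adjusted p = 0.0842). Cytosolic ribosomal proteins were lower for 77 of 80 that differed (median -0.34, adjusted p = 1.73e-10), a call that ended without Hopx CR replicate 1 (median -0.10, adjusted p = 0.135). Paneth cell genes were lower for 18 of 20 (median -0.68, adjusted p = 8.59e-04), and the call ended without Hopx AL replicate 1 (median -0.03, adjusted p = 0.616) or Hopx CR replicate 2 (-0.50, adjusted p = 0.0842), and with the length and GC correction (-0.47, adjusted p = 0.137). Cholesterol synthesis was lower for 21 of 27 (median -0.32, adjusted p = 6.14e-04), but not without Hopx AL replicate 1 (-0.09, adjusted p = 0.357) or Hopx CR replicate 1 (-0.15, adjusted p = 0.348). Within isolations the cholesterol list stood at -0.69 in 1 and 0.17 in the other. With a Hopx library left out, the medians ranged over -1.25 to -0.371 (enteroendocrine) and -0.634 to -0.103 (ribosomal protein). They ranged over -1.09 to -0.0336 for Paneth cell and -0.519 to -0.0894 for cholesterol synthesis. Glycolysis genes were higher for 17 of 20 (median 0.31, adjusted p = 0.00702), but not past the threshold without Hopx AL replicate 2 (0.19, adjusted p = 0.246) or Hopx CR replicate 2 (0.19, adjusted p = 0.0676). Circadian clock genes were higher for 17 of 21 (median 0.52, adjusted p = 0.0236), with Per1 at 1.38. That call ended without Hopx AL replicate 2 (median 0.31) or Hopx CR replicate 1, or with the length and GC correction (0.42, adjusted p = 0.137). The circadian median ranged over 0.000431 to 1.06 with a Hopx library left out.

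Oxidative phosphorylation genes were lower for 58 of 77 (median -0.17, adjusted p = 0.0306), but the call ended without Hopx AL replicate 2 (-0.10, adjusted p = 0.287), and the median turned to 0.06 without Hopx CR replicate 1 and to 0.02 with the length and GC correction. It was 0.09 on the TPM scale, where the median of all genes shifted by 0.27 and the list stayed below it. With isolation as a block edgeR called 0 genes in Hopx CR against AL, with 1575 at an unadjusted p under 0.05 against 1349 without it, and DESeq2 called 144, 89 higher and 55 lower. The count of 2 was 1 without Lgr5 AL replicate 2, any Lgr5 CR library, Hopx AL replicate 1 or Hopx CR replicate 1. On the log2(TPM + 1) scale 4 genes passed, 1 higher and 3 lower.

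**Figure D2:**
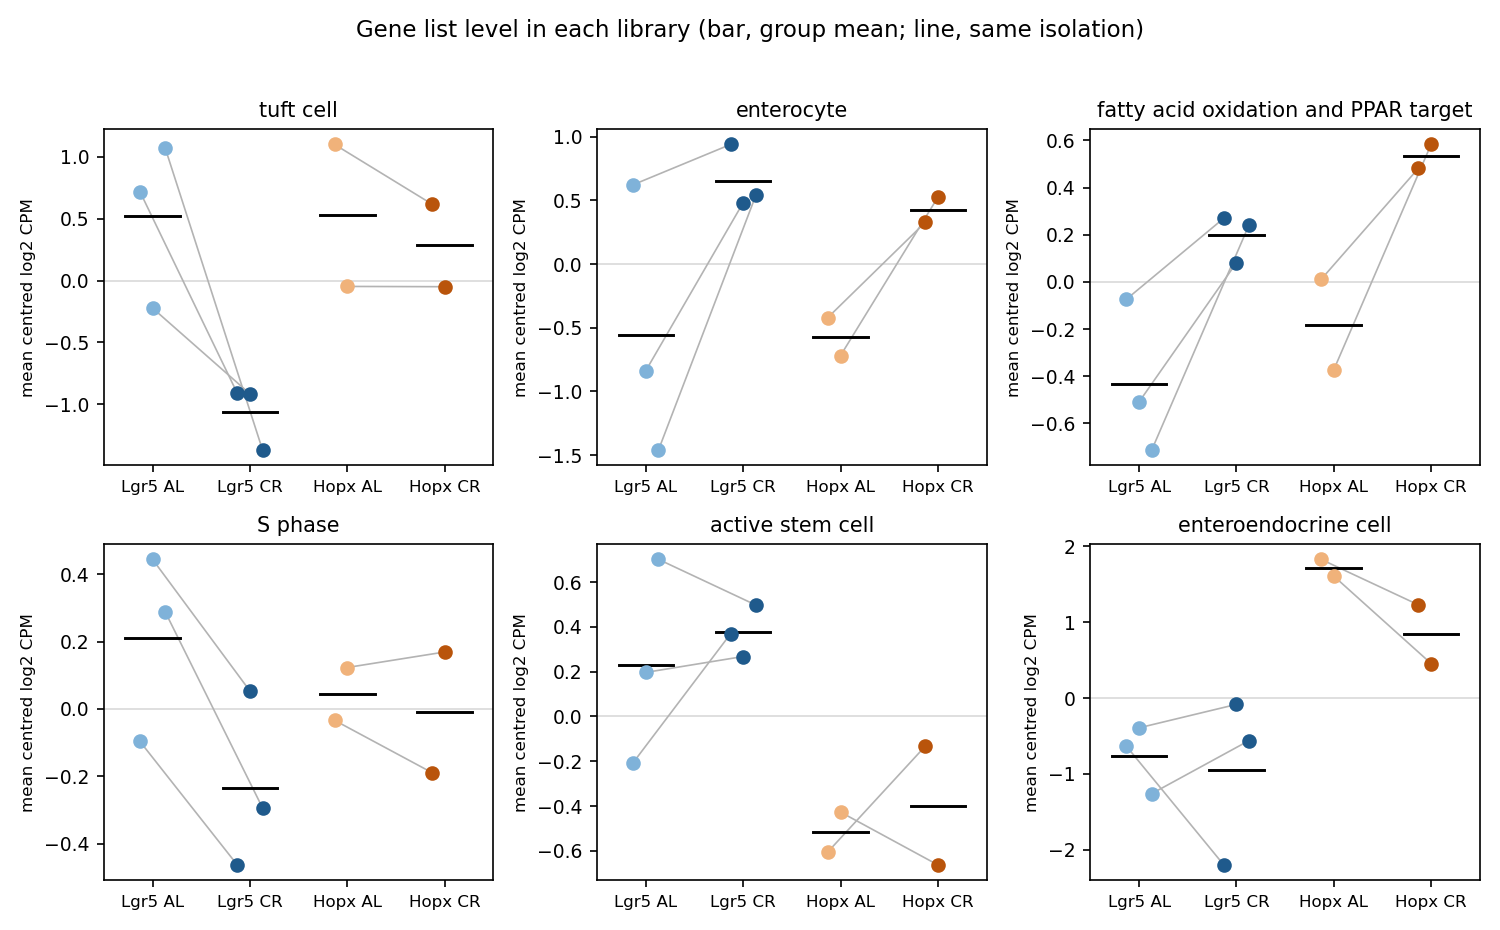
Level of 6 gene lists in each library, as the mean over the list of log2 CPM centred on each gene's mean over the 10 libraries (vertical axes), by group (horizontal axes), with points for libraries, bars for group means and thin lines for the same isolation. Tuft cell genes are lower and enterocyte genes higher in the CR animal of each of the 3 Lgr5 isolations, and enteroendocrine genes are higher in all 4 Hopx libraries than in all 6 Lgr5 libraries.

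The diet responses of the populations, which share no library, were then set side by side. At an unadjusted p under 0.05 in both, 204 genes were higher under CR in both populations where 47.7 would be shared by independent lists, 77 were lower in both against 20.7, and 18 went opposite ways against 63.5. Across all genes the log2 fold changes correlated weakly (r = 0.177, rho = 0.301), and genes are not independent replicates. Apob, Cyp3a11 and Acadl were among the list members with positive values in both. By the interaction test, which asks whether the diet effect differs between populations, 1 gene passed, Gm10698 (adjusted p = 0.00186), with 747 genes at an unadjusted p under 0.05 where 792 would come by chance and 40 called by DESeq2. With isolation as a block edgeR called 0, with 764 at an unadjusted p under 0.05. The count of 1 became 2 without Lgr5 AL replicate 1, Lgr5 AL replicate 3 or Hopx CR replicate 2.

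Genes with the smallest interaction p did not pass (adjusted p of 0.88 or more). They include Capn15, Tmprss15 (-2.55), Rbm45 (-2.84), Rptor (1.20), Iba57 (1.13), Zfp574 (0.94), Hebp1 (-2.95), the aldo-keto reductase Akr1b8 (-4.21), Papss2 (-1.28) and Zc3h4 (1.53). Of 34 lists, 9 passed camera for the interaction, and none held with an estimated correlation (smallest adjusted p = 0.94) or with fry (0.982). The tuft cell list differed the most between populations (median 1.54, adjusted p = 1.57e-13, 20 of 21 members above 0), its median in Hopx cells being -0.19 with CR. That Hopx value did not pass (adjusted p = 0.459), and it moved with single libraries. It passed at 0.59 without Hopx AL replicate 1 (adjusted p = 0.0356), at -0.76 without Hopx AL replicate 2 (adjusted p = 1.09e-04) and at -0.64 without Hopx CR replicate 1 (adjusted p = 0.0121). It was 0.18 on the TPM scale, where the median of all genes shifted by 0.27. Neither the enterocyte list (0.17, adjusted p = 0.693) nor the fatty acid oxidation list (0.10, adjusted p = 0.176) passed for the interaction. The enterocyte list passed at -0.68 without Lgr5 AL replicate 1 (adjusted p = 3.5e-09) and at 0.50 without Lgr5 AL replicate 3 (adjusted p = 0.0271). The fatty acid oxidation list passed at 0.16 without Lgr5 AL replicate 3 (adjusted p = 0.00865) and at 0.27 without Hopx AL replicate 1 (adjusted p = 0.00185). It also passed at 0.09 with the length and GC correction (adjusted p = 0.0455) and 0.19 with sex as a term (adjusted p = 0.0276).

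**Figure D3:**
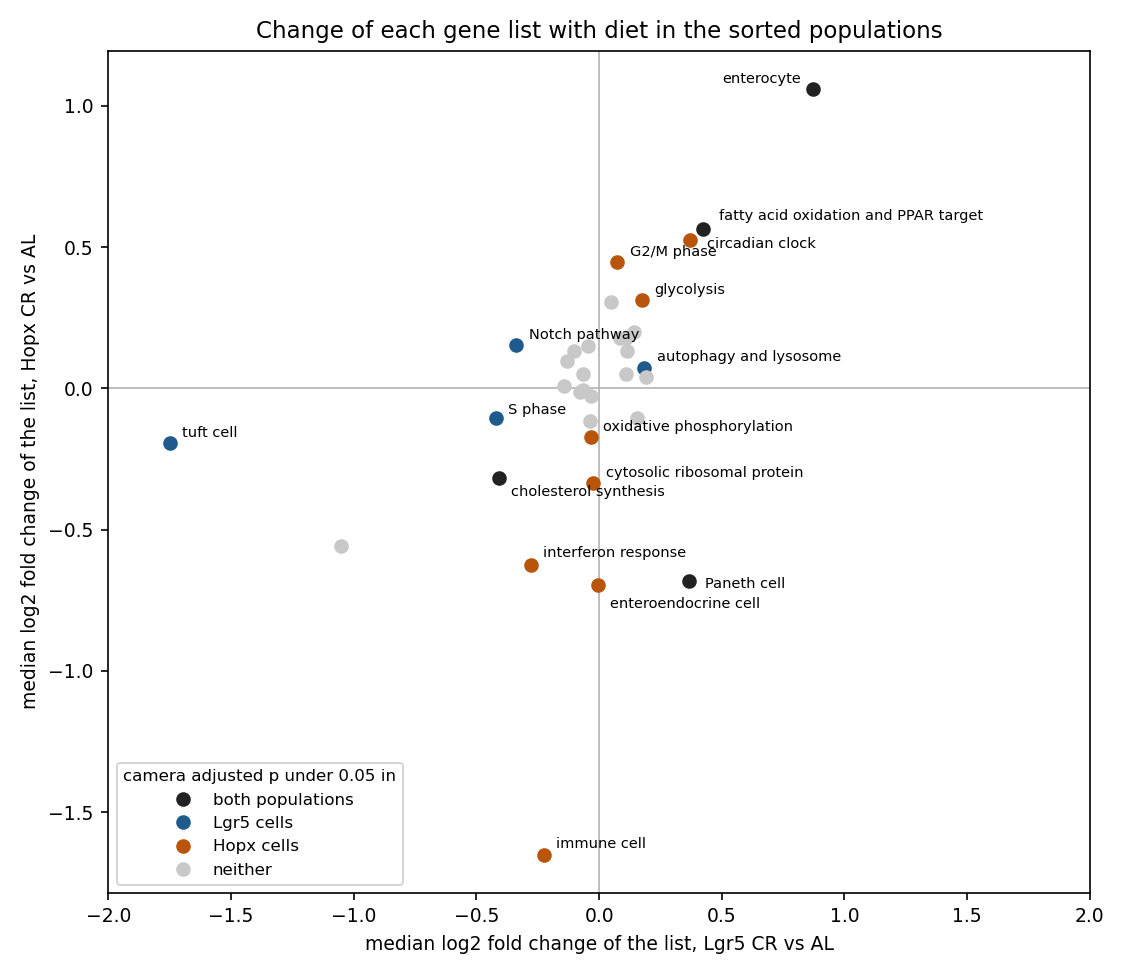
Median log2 fold change with calorie restriction of each gene list in Lgr5 cells (horizontal axis) and Hopx cells (vertical axis), coloured by the population in which camera passed at its preset correlation. Enterocyte (0.87 and 1.06) and fatty acid oxidation (0.42 and 0.57) lie upper right, cholesterol synthesis (-0.41 and -0.32) lower left, and tuft cell (-1.75 and -0.19) far left.

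The third question was how Hopx and Lgr5 cells, sorted as reserve and active stem cells, differ in animals with free access to food. In Hopx AL, Gm9765 (7.43, adjusted p = 0.0123) and the ribosomal pseudogene Rps13-ps1 (1.60 ± 0.93 to 69.0 ± 13 CPM, adjusted p = 0.0174) were higher and Gm5499 (8.78 ± 2.4 to 0.0583 ± 0.0088 CPM, -7.15, adjusted p = 0.0123) was lower than in Lgr5 AL. All 3 are predicted genes or pseudogenes and are uncertain. The 10 next genes all stood at adjusted p = 0.0581 and did not pass. They are the AP-1 factor Jun (-1.57, 235 ± 24 to 79.3 ± 13 CPM), the fatty acid binding protein Fabp5 (3.29), the endocrine transcription factor Isl1 (3.29), Rbm45 (2.84), the membrane protease Mmp15 (-1.07), Asph (1.38), Sphkap (3.62), the cannabinoid receptor Cnr1 (4.35), the matrix gene Fbln2 (2.31) and the Wnt target Sp5 (-1.73). Ascl2 differed by -2.11 (adjusted p = 0.0639), Lgr5 by -0.98 (adjusted p = 0.34), Olfm4 by -0.91 (adjusted p = 0.209), Hopx by -0.23 (adjusted p = 0.541) and Rptor by -0.99 (adjusted p = 0.0655).

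Of 34 lists, 12 passed camera between Hopx AL and Lgr5 AL, 7 higher and 5 lower. No call held with an estimated correlation (smallest adjusted p = 0.786) or with fry (0.262). Enteroendocrine genes were higher for 31 of 32 (median 1.96, adjusted p = 3.14e-25; 20 adjusted over the list alone, 0 over all genes), with the hormone gene Gip at 4.58, the granule protein Scg2 at 3.32 and Isl1 at 3.29. All 20 Paneth cell genes were higher (median 1.64, adjusted p = 9.64e-14, with 11 adjusted over the list alone and 0 over all genes), among them Defa24 (1.85) and Lyz2 (2.74), which is also on the immune cell list. Active stem cell genes were lower for 37 of 39 (median -0.85, adjusted p = 3.03e-15; 14 adjusted over the list alone, 0 over all genes). The reserve stem cell list did not pass, with 6 of 17 higher (median -0.23, adjusted p = 0.204). It passed without Hopx AL replicate 1 (-0.80, adjusted p = 0.0481). Cytosolic ribosomal proteins were higher for 77 of 81 (median 0.66, adjusted p = 1.87e-19; 37 adjusted over the list alone, 0 over all genes), with Rpl21 at 1.28, and had a median of -0.14 on the TPM scale. Genes of oxidative phosphorylation were higher for 70 of 77 (median 0.64, adjusted p = 1.04e-15; 29 adjusted over the list alone, 0 over all genes), with Ndufb9 at 0.85, and had a median of -0.11 on the TPM scale, where the median of all genes shifted by -0.73 and both lists stayed above it. These 5 lists passed with any single library of the groups left out. The active stem cell median was -0.50 without Lgr5 AL replicate 3. Goblet cell genes were higher for 16 of 19 (median 1.03, adjusted p = 5.61e-05; 4 adjusted over the list alone, 0 over all genes), with Tff3 at 1.85 and Spink4 at 1.70, a call that ended without Hopx AL replicate 1 (median 0.32, adjusted p = 0.287).

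The other 6 of these lists passed less firmly. The Wnt target list (median -0.21, adjusted p = 0.00778) lost its call without Lgr5 AL replicate 3 (-0.11, adjusted p = 0.0915) or Hopx AL replicate 2 (adjusted p = 0.06), where the median was larger (-0.33). It was -0.01 with the length and GC correction (adjusted p = 0.315). The S phase list (-0.21, adjusted p = 0.0305) lost its call without Lgr5 AL replicate 2 (-0.08, adjusted p = 0.232), Lgr5 AL replicate 3 (-0.175, adjusted p = 0.105) or Hopx AL replicate 1 (-0.13, adjusted p = 0.199). The list of G2 and M phase (-0.19, adjusted p = 0.0256) lost it without Lgr5 AL replicate 2 (-0.06, adjusted p = 0.419) or Hopx AL replicate 1 (-0.14, adjusted p = 0.875). Ribosome biogenesis (-0.26, adjusted p = 0.0389) lost it without Lgr5 AL replicate 2 (-0.14, adjusted p = 0.169), Lgr5 AL replicate 3 (-0.23, adjusted p = 0.143) or Hopx AL replicate 2 (-0.11, adjusted p = 0.148). The calls of cholesterol synthesis (median 0.31, adjusted p = 0.0255) and the unfolded protein response (0.24, adjusted p = 0.0136) ended without Lgr5 AL replicate 3 (0.21 and 0.15, adjusted p = 0.221 and 0.143) or Hopx AL replicate 1 (0.06 and 0.05, adjusted p = 0.707 and 0.644). The cholesterol synthesis call also ended with the length and GC correction (adjusted p = 0.0547), which left its median at 0.305. On the TPM scale cholesterol synthesis and the unfolded protein response stood at -0.41 and -0.57, where the median of all genes shifted by -0.73 and both lists stayed above it.

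Isolation and reporter line cannot be told apart from population here, since 0 isolations hold both. At an unadjusted p under 0.05 edgeR gave 2801 genes, DESeq2 called 1104 (455 higher, 649 lower), and on the log2(TPM + 1) scale 93 genes were higher and 3652 lower. The TPM fit had no scaling between libraries and the median of all genes shifted by -0.73 in it, so the excess of lower genes goes with that shift. The edgeR count of 3 was 110 without Lgr5 AL replicate 1, 0 without Lgr5 AL replicate 2, 9 and 5 without Lgr5 CR replicates 1 and 2, 6 and 19 without Hopx AL replicates 1 and 2, and 27 without Hopx CR replicate 1 or 2.

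The same comparison was made under calorie restriction. Rps13-ps1 was higher in Hopx CR than in Lgr5 CR (1.46 ± 0.81 to 79.4 ± 4.7 CPM, 5.81, adjusted p = 0.0107). Gm10698 (adjusted p = 4.79e-04) and Gm5499 (adjusted p = 0.0032) had no counts in Hopx CR and were at least 517-fold and at least 357-fold lower there than in Lgr5 CR. Genes next to the threshold were Afap1l1 (-1.60) and Jun (-1.46), both at adjusted p = 0.0778, and the tyrosine-degrading enzyme Fah (2.12) and the complex I assembly gene Timmdc1 (-2.37), both at adjusted p = 0.0794. Further genes were Ccdc3 (-1.90, adjusted p = 0.0928), Fabp5 (2.64) and the proglucagon gene Gcg (3.73), both at adjusted p = 0.172, and Isl1 (2.53), Tbc1d23 (-1.49) and Lcp1 (-0.87), at adjusted p = 0.202. Hopx stood 0.60 log2 units lower in the Hopx cells (99.1 CPM against 150 CPM, adjusted p = 0.572) and Olfm4 differed by -1.27 (adjusted p = 0.541).

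Of 34 lists, 16 passed camera between Hopx CR and Lgr5 CR, 11 higher and 5 lower. No list held with an estimated correlation (smallest adjusted p = 0.422) or fry (0.48). Enteroendocrine genes were higher for 31 of 32 (median 1.26, adjusted p = 1.65e-27; 10 adjusted over the list alone, 0 over all genes), tuft cell genes for 20 of 21 (1.49, adjusted p = 6.14e-18; 12 and 0) and goblet cell genes for 18 of 19 (0.88, adjusted p = 3.09e-10; 5 and 0). Active stem cell genes were lower for 38 of 39 (-0.75, adjusted p = 8.95e-25; 11 and 0). Genes of oxidative phosphorylation were higher for 76 of 77 (0.46, adjusted p = 3.81e-21) and of the unfolded protein response for 20 of 25 (0.24, adjusted p = 0.00158; -0.05 on the TPM scale), while all 8 MHC class II genes were lower (-0.47, adjusted p = 0.00158). Fatty acid oxidation was higher for 33 of 39 (0.27, adjusted p = 3.39e-06), with a median of -0.03 on the TPM scale, where the median of all genes shifted by -0.28 and each list stayed above it. These 8 lists passed with any single library of the groups left out, though several moved. Oxidative phosphorylation was 0.20 and active stem cell -0.50 without Hopx CR replicate 2, enteroendocrine 0.83 without Lgr5 CR replicate 1, and goblet cell 0.55, tuft cell 0.91 and active stem cell -1.15 without Hopx CR replicate 1.

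Calls for cytosolic ribosomal proteins (0.29, adjusted p = 3.09e-10; -0.02 on the TPM scale), Wnt targets (-0.31, adjusted p = 3.78e-05) and cholesterol synthesis (0.36, adjusted p = 4.6e-06) ended without Hopx CR replicate 2 (0.03, -0.21 and 0.08, adjusted p = 0.677, 0.365 and 0.185). S phase (0.19, adjusted p = 0.00892; -0.08 on the TPM scale) ended without Lgr5 CR replicate 1 (0.02, adjusted p = 0.484) or Hopx CR replicate 2 (0.03, adjusted p = 0.749). Immune cell markers (-0.97, adjusted p = 0.0303) ended without Lgr5 CR replicate 1 (-0.46, adjusted p = 0.432) or Hopx CR replicate 1 (-0.47, adjusted p = 0.756). With a library left out the medians ranged over 0.0316 to 0.556 (ribosomal proteins), -0.641 to -0.206 (Wnt targets) and -1.86 to -0.461 (immune cell markers). The lists of Paneth cell (0.46, adjusted p = 0.031), G2 and M phase (0.14, adjusted p = 0.0465, and -0.14 on the TPM scale) and dissociation genes (-0.26, adjusted p = 0.0478) passed narrowly. Of these the Paneth cell and G2 and M phase calls ended without Lgr5 CR replicate 1 (medians 0.29 and 0.11, adjusted p = 0.212 and 0.0858), Lgr5 CR replicate 2 (0.43 and 0.03, adjusted p = 0.0518 and 0.525) or Hopx CR replicate 1 (0.00493 and 0.0537, adjusted p = 0.652 for each). The dissociation call ended without Lgr5 CR replicates 2 or 3 (-0.22 and -0.21, adjusted p = 0.107 and 0.192) or Hopx CR replicates 1 or 2 (-0.185 and -0.122, adjusted p = 0.279 and 0.0583). The length and GC correction ended these 3 calls as well (adjusted p = 0.229, 0.0505 and 0.123) while their medians stayed at 0.41, 0.15 and -0.28, and RLE scaling the dissociation call (-0.27, adjusted p = 0.0514). The lists with a negative median on the TPM scale stayed above that of all genes. DESeq2 called 190 genes between Hopx CR and Lgr5 CR, 998 had an unadjusted edgeR p under 0.05, and on the log2(TPM + 1) scale 13 passed, 6 higher and 7 lower. The edgeR count of 3 was 7 without Lgr5 AL replicate 3, 5 without Hopx AL replicate 1 or 2, and 1 without Hopx CR replicate 1.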

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

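In some results the diet effect differed between Hopx and Lgr5 cells by the interaction test, and they come first. The fits with 1 library left out were fixed before the data were examined. The second lists, the length and GC correction, the term for sex and the use of each fit as a test of an explanation were chosen after the patterns had been seen. Predictions were written before each test was run, except that of isolation or reporter line, which was written after. Gm10698 is the gene with a diet effect that differed between populations (edgeR interaction adjusted p = 0.00186), with no counts in either Hopx CR library and 10.3 CPM in Lgr5 AL, 12.3 in Lgr5 CR and 6.73 in Hopx AL. With isolation as a block edgeR called 0 genes for the interaction, so this call was lost as well. Lists whose members differed by camera at its preset correlation had positive medians for the mixed Notch pathway list (0.316), S phase (0.425), G2 and M phase (0.33) and tuft cell markers (1.54). They had negative medians for cytosolic ribosomal proteins (-0.296, and 0.187 on the TPM scale), interferon response (-0.316, and 0.139 on the TPM scale, where the median of all genes shifted by 0.455 and both lists stayed below it), Paneth cell (-0.963), enteroendocrine (-0.794) and immune cell markers (-1.36). The smallest adjusted p over these lists with an estimated correlation was 0.94. The S phase, tuft cell, Paneth cell and immune cell calls held with any single library left out, but their medians moved. S phase ranged over 0.165 to 0.544 (smallest without Hopx CR replicate 2), tuft cell over 0.915 (without Hopx CR replicate 1) to 2.45 (without Hopx AL replicate 1), Paneth cell over -1.67 (without Hopx CR replicate 1) to -0.37 (without Hopx AL replicate 1) and immune cell over -2.53 (without Lgr5 AL replicate 1) to -0.766 (without Hopx CR replicate 1). The G2 and M phase call ended without Hopx AL replicate 1 (0.21, adjusted p = 0.15) and the Notch call without Hopx AL replicate 2 (0.311, about its size with all libraries, adjusted p = 0.323) or Hopx CR replicate 1 (0.123, adjusted p = 0.466). The ribosomal protein call ended without Lgr5 CR replicate 2 (-0.125, adjusted p = 0.197), Hopx AL replicate 2 (-0.148, adjusted p = 0.133) or Hopx CR replicate 1 (-0.103, adjusted p = 0.805). The enteroendocrine call ended without Lgr5 AL replicate 3 (-0.59, adjusted p = 0.0807), Lgr5 CR replicate 2 (-0.389, adjusted p = 0.413), Lgr5 CR replicate 3 (-0.64, adjusted p = 0.0611) or Hopx CR replicate 2 (-0.335, adjusted p = 0.696). The interferon response call ended without Lgr5 AL replicate 2 (-0.212, adjusted p = 0.159), Lgr5 AL replicate 3 (-0.0873, adjusted p = 0.171), Lgr5 CR replicate 2 (-0.138, adjusted p = 0.117) or Hopx AL replicate 2 (-0.17, adjusted p = 0.105). It also ended without Hopx CR replicate 2 (adjusted p = 0.0633), where the median was larger (-0.413). G2 and M phase ranged over 0.127 to 0.639 with a library left out. The length and GC correction ended the Notch (0.139, adjusted p = 0.116) and ribosomal protein calls (-0.189, adjusted p = 0.105). Sex as a term ended the ribosomal protein (-0.152, adjusted p = 0.112) and interferon response calls (-0.289, adjusted p = 0.0792).

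The first pattern weighed is the low level of tuft cell markers in Lgr5 CR (median -1.75), next to -0.19 in Hopx CR and an interaction median of 1.54. Against a single library as the cause, the median kept at least 87.4% of its value with any Lgr5 library left out, and against a trend with transcript length and GC content it kept 100% after that trend was removed. Fewer tuft cells in the CR sorts may account for it: of a second list of 24 tuft cell genes that shares no member with the first, 91.7% were lower in Lgr5 CR (median -1.38, camera p = 3.82e-18, p = 0.0366 with an estimated correlation), Hpgds by -2.50, Lrmp by -1.80 and Siglecf by -1.86. The most abundant members of the first list include Sox9, which stem cells also express (221 and 199 CPM in Lgr5 AL and CR), and Avil (124 and 34.3). Of the 21 members of that list, 17 were at 5 CPM or more in Lgr5 AL. How fully the sort for the Lgr5 reporter left tuft cells out was not measured. Fewer cells and lower expression per cell were not told apart, and the second list in Hopx CR had a median of -0.18 with 20 of 24 lower and did not pass.

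The second pattern is the higher level of enterocyte and fatty acid oxidation genes under CR in both populations. A second list of 28 enterocyte genes that shares no member with either list was higher for 85.7% of members in Lgr5 CR (median 0.59, camera p = 3.36e-08) and 89.3% in Hopx CR (0.73, camera p = 2.24e-08), with p = 0.219 and 0.22 with an estimated correlation, so more differentiated enterocytes in the CR sorts are a candidate explanation, as is higher expression of the same genes per cell. How fully the sorts for the Lgr5 and Hopx reporters left enterocytes out was not measured. Npc1l1 stood at 0.63 and 1.65 and Abcg8 at 0.96 and 1.25. The abundant enterocyte genes Apoa4 (3690 and 6980 CPM in Lgr5 AL and CR) and Apoa1 (4150 and 4880) were high in every group, and all 33 members of the first list were at 5 CPM or more in Lgr5 AL. With sex as a term the fatty acid oxidation list's median in Hopx cells was 124% of its value without it. That term cannot decide, because Y-linked transcripts were near 0 only in both animals of isolation 3 and in Hopx CR replicate 1. The animals of isolations 1, 2, 3 and 5 matched in Y-linked transcripts. There the list was higher under CR by 0.344, 0.59, 0.955 and 0.956 log2 units, which argues against sex as its cause in these isolations. In isolation 4, whose animals differed, it was higher by 0.471. No single library can account for the whole pattern, since the populations share none, the fatty acid oxidation list was higher in the CR animal of all 5 isolations, and its call held with any library left out (largest adjusted p = 1.98e-06). How much of its size rests on 1 library is left open in both populations. In Lgr5 cells the median kept 69.7% of its value without Lgr5 CR replicate 1 (0.29) and 74.4% without Lgr5 AL replicate 3. In Hopx cells it kept 73% without Hopx AL replicate 2.

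The third pattern is the higher level of ribosomal protein and oxidative phosphorylation genes in Hopx AL than in Lgr5 AL. With each library's trend with transcript length and GC content removed, the ribosomal protein median kept 68.9% of its value (0.66 to 0.46, camera adjusted p = 4.87e-09) and that of oxidative phosphorylation 69.9%, so part of the difference could follow from that trend. The part that remained is not from the trend as it was fitted, and the shares lie between the bounds of 50% and 75% set before the test, so the trend is neither shown nor excluded as the main cause. After the correction the lowest Hopx AL library (0.0422) lay under the highest Lgr5 AL library (0.0641) for ribosomal proteins, and above it for oxidative phosphorylation (0.132 and -0.0303). Isolation and reporter line stay open too, since 0 isolations hold both populations, as does the biological difference between the populations, which was not tested apart from them. The Paneth cell and enteroendocrine lists were higher in Hopx AL as well, with Lyz1 at 71500 CPM against 19100 in Lgr5 AL and Chgb at 2470 against 783. A different mix of cells in the sorts was not tested for this pattern.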

How the results depend on the processing

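The count of called genes was the result that moved the most with the processing. The TPM fits had no scaling between libraries, so their counts carry the shift of all genes given at the end of this paragraph. The cause of the other moves was not tested. In the order Lgr5 CR against AL, Hopx CR against AL, interaction, Hopx against Lgr5 under AL and under CR, the counts of 3, 2, 1, 3 and 3 were 1, 2, 1, 3 and 3 with RLE or upper-quartile scaling and 83, 7, 3, 194 and 24 with no low-count filter. They were 3, 2, 1, 61 and 4 with a 10 CPM filter, 360, 144, 40, 1104 and 190 with DESeq2, 33, 4, 4, 3745 and 13 on log2(TPM + 1), and 24, 3, 2, 3886 and 13 on log2(TPM + 0.1). With only the groups compared they were 4, 2, 4 and 12 without the interaction. For Hopx CR against AL these 2 were 1 higher and 1 lower, where the main fit called 2 lower. Isolation as a block gave 0, 0 and 0 for the first 3, and isolation as a random effect 9 and 4 for the last 2. The length and GC correction gave 0, 2, 1, 3 and 3 and sex as a term 0, 1 and 1. With 1 library left out in turn the counts ranged over 0 to 109, 1 to 3, 1 to 2, 0 to 110 and 1 to 7, and without both libraries of Lgr5 replicates 1, 2 or 3 the first was 16, 0 and 0. The lists past camera ranged over 8 to 15, 11 to 15, 7 to 16, 9 to 16 and 13 to 16 with a library left out, and were 0, 0, 0, 0 and 0 with an estimated correlation. For Tmprss15, Papss2 and Mt2 the fold change kept its direction under each alternative tabulated for single genes (RLE, DESeq2, log2(TPM + 1), block, sex, length and GC, and single libraries left out). The oxidative phosphorylation list in Hopx CR against AL turned to 0.0185 with the length and GC correction and 0.0681 with sex as a term, and ranged over -0.462 to 0.0629 with a library left out. Other ranges with a library left out were -0.221 to 0.22 (mTORC1 and ATF4 targets, Hopx CR against AL), -0.759 to 0.594 (tuft cell, Hopx CR against AL), -0.788 to 0.355 (enterocyte, Hopx against Lgr5 under AL) and -0.682 to 0.495 (enterocyte, interaction). G2 and M phase in Hopx against Lgr5 under AL ranged over -0.527 to -0.0636, with camera's direction turned without Hopx AL replicate 1 (-0.141). With sex as a term the Paneth cell, cholesterol synthesis and circadian clock calls in Hopx CR against AL ended (adjusted p = 0.103, 0.103 and 0.367). RLE and upper-quartile scaling moved the median of all genes by less than 0.1, and log2(TPM + 1) by -0.192, 0.268, 0.455, -0.73 and -0.282.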

Other observations

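The xenobiotic gene families and the tests of other splits were chosen after the first results had been seen, with the prediction for each written before its test was run. Families of genes that handle foreign compounds were chosen for their higher level in Lgr5 CR, so their values there are given without a test. The enterocyte genes, a list that shares Cyp3a11 with them, were higher under CR as well (medians 0.87 in Lgr5 and 1.06 in Hopx cells). Of 69 measured glutathione S-transferase, UDP-glucuronosyltransferase, cytochrome P450 and metallothionein genes, 59 were higher in Lgr5 CR (median 0.92), and 1 passed over all genes, Mt2. In Hopx CR 51 were higher (median 0.69, camera p = 5.68e-10, p = 0.0392 with an estimated correlation), 0 adjusted over the list alone, with 21 higher and 1 lower at an unadjusted p under 0.05. The cytochrome P450 genes Cyp2c29 and Cyp2c55 stood at 4.34 and 3.11 in Lgr5 cells and at 5.53 and 3.56 in Hopx cells, Cyp2j6 at 1.02 and 1.14, Gstm4 at 1.48 and 1.06, Gsta1 at 2.44 and 0.51 and the glucuronosyltransferase Ugt2b5 at 3.15 and 0.88. The interaction median was -0.328 (47 of 69 lower, camera p = 0.00146, p = 0.222 with an estimated correlation), but the choice by the change in Lgr5 cells pushes that value below 0 by itself. These families have many similar members and single members are uncertain.

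Of the 31 members at an unadjusted p under 0.05 in Lgr5 cells, all of them higher there, 29 were higher in Hopx CR (median 0.94). This count was made after the other results were seen and was not tested against the other genes. The 31 were picked by the Lgr5 contrast of the fit to all 10 libraries. The Hopx libraries thus entered the pick through the filter, the scaling and the shared spread. The other 38 had a median of 0.102 in Hopx CR (22 higher, 16 lower, camera p = 0.0751, p = 0.294 with an estimated correlation), but they were selected for a lack of change in Lgr5 cells, so that value cannot tell whether the response is shared. A response of the families and a larger share of enterocytes under CR were not told apart.

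The 3 genes called in Lgr5 CR against AL were set against all 10 ways of splitting the 6 Lgr5 libraries into 3 and 3. The real split called 3 genes and the highest other 2, with 1 of 10 splits calling as many, and 10 splits are too few for a share under 0.05. With DESeq2 the real split called 360 genes, the highest other 231, and the highest among the other splits that part all 3 isolations 21. At an unadjusted p under 0.05 the real split gave 1549 genes and the highest other 2079. For gene lists the real split passed 8 and the highest other 19, or 15 among the other splits that part all 3 isolations. All 10 of 10 splits passed as many, so the number of lists past camera does not set the real split apart. The cause was not tested.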
